A study of Mus musculus with 17 samples.

How the data were processed

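Bulk RNA-seq was measured in 14 mouse skin ILC libraries in 6 groups, and single-cell RNA-seq in 3 libraries. Per the labels, the authors aligned reads to the mouse genome mm10 with HISAT2 2.1.0 and counted them per gene with featureCounts from Subread. The deposited bulk values were raw counts per gene, not normalised, with the gene's exon coordinates beside them, for 54446 Ensembl genes, of which 54409 had a symbol in the annotation used here. The deposited single-cell values were raw whole-number counts per gene and cell, not normalised. The single-cell platform and the way cells were called were not stated in the labels. Gene coordinates differed for 853 gene models between the fate-map and the tamoxifen file sets, with no difference in gene length, so counts were joined by gene ID within each set.

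Bulk counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with too few counts were removed with edgeR's filterByExpr, library sizes were scaled with TMM factors, and a quasi-likelihood model was fitted. A single model held the 10 fate-map libraries (17456 genes tested), with each comparison and the interaction as a contrast. A separate model held the 4 tamoxifen libraries (13272 genes tested). A gene was called where its Benjamini-Hochberg adjusted p over all genes tested was under 0.05. Log2 fold changes are given with the SE of the fit, and CPM values are counts scaled to library sizes with TMM factors, with their SD between libraries. Summed CPM of gene lists were not TMM-scaled. Where a group had 0 counts of a gene, the fold is a lower bound against 3 counts over the group. Where a group had 1 to 3 counts, the ratio is given with its 95% counting interval. The fitted log2 fold change of such genes depends on edgeR's default prior count and is no bound. Intervals and bounds cover counting error only.

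Gene lists were tested with camera from limma 3.58.1 at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. The same lists were tested with a correlation estimated from the data and with fry. The 26 lists covered ILC2, ILC3 and type 17, ILC1 and NK, ILC progenitor and early lymphoid, signals to epithelium and hair follicle, homing and residency, cytokine receptors, cell cycle, survival and apoptosis, glycolysis, lipid metabolism, interferon response, immediate early and stress, antigen presentation by MHC class II, T cell, B cell, myeloid, mast cell and basophil, keratinocyte, fibroblast, endothelial, melanocyte and Schwann cell, erythroid, sex-linked check, ribosomal proteins and mitochondrially encoded genes. The erythroid list had too few tested members in the tamoxifen libraries to be tested there.

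Genes were named by a rule. Gata3 was always named. Another gene of the rule is not used here. From the lists for ILC2, ILC3, ILC1, homing, signals to epithelium and progenitors, the 3 tested members with the smallest p were named, and from other lists 2 members where camera called the list. The 5 highest and 5 lowest log2 fold changes were added among called genes with a mean CPM of at least 10 and no overlap between the groups' libraries, leaving out gene models without a name, antigen receptor segments and sex-linked genes. For the interaction these 10 genes were named with Gata3. For single cells, readout genes were named (Gata3, Tbx21, Areg, Il5, Il13, Il17a, Il17f, Il22, Ifng and Csf2), with the 10 highest and 10 lowest ratios among genes with at least 100 summed counts and a log2 ratio of at least 1 in either direction. Unnamed gene models and ribosomal, mitochondrial and haemoglobin genes were left out of those ratios. The sample groups, the comparisons, the gene lists, the naming rule and the alternatives were chosen before the data were examined, except where the closing section says otherwise.

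Single cells were analysed in Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Cells with under 200 genes or over 10% mitochondrial counts were removed, as were predicted doublets. The skin library listed 37 mitochondrially encoded genes and the dorsal libraries listed 0, so the mitochondrial limit acted on the skin library alone. Cells were scaled to 10000 counts, and 2000 variable genes, 30 principal components, 15 neighbours, Leiden clustering at resolution 0.5 and seed 0 were used. The readout genes were kept out of the clustering. The dorsal libraries were clustered together and the skin library by itself. Clusters were named from the fixed marker lists, or left unnamed where no list or more than 1 list fitted. With 1 library per condition no p-value was computed: ratios of summed counts carry 95% Poisson counting intervals. List medians between days were placed among 10000 random lists matched on expression, taken from 50 neighbours on each side. The log2 ratios behind these medians used a prior count of 0.5. Cell shares carry exact Clopper-Pearson 95% intervals.

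The alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, no filter on low counts, a mean CPM of at least 5, only the libraries of the 2 groups compared, replicate number as a block, sequencing lane as a covariate, a log2 fold change of at least 1, and leaving out each library in turn. For single cells they were keeping doublets, at least 500 genes per cell, Leiden resolutions of 0.3 and 1.0, clustering each library alone, keeping the readout genes, thinning cells to 1000 counts, keeping ILC classes alone, and leaving out ribosomal and mitochondrial genes. The bulk procedure was tested on simulated data with 200 changed genes per comparison, all with a mean CPM of at least 10. Recovery of scarcer genes was not tested. It recovered 13.4%, 15.3%, 9.84%, 4.69%, 1.45% and 1.43% of 2-fold changes in the 6 comparisons in the order of the report, and 79.7%, 84.1%, 85.9%, 82.8%, 65.7% and 53.5% of 8-fold changes. Unchanged simulated genes called in the 6 comparisons numbered 10, 5, 0, 1, 1 and 4. The single-cell list test placed all 20 simulated lists with a 1.5-fold change above the random range and 0 of 20 unchanged ones. Total counts ranged from 14450612 to 44098274 in the bulk libraries. No library was a copy of another of its bulk group, and pairs across groups were not checked. Figures were drawn with matplotlib 3.10.9.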

Results

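Skin innate lymphoid cells (ILCs), tissue lymphocytes without rearranged antigen receptors, were profiled from mice in 14 bulk RNA-seq libraries and 3 single-cell RNA-seq libraries. Per the labels, live, lineage-negative, γδ T cell receptor-negative, CD90-positive cells were sorted from skin. The first 10 bulk libraries came from mice with a fate-map (fm) reporter, which keeps a cell marked after the gene that drives it is switched off. Reporter-positive and reporter-negative cells were sorted from intact mice (fm_pos, n = 2, and fm_neg, n = 2). They were sorted too from mice labelled as carrying a floxed Gata3 allele (fm_pos_Gata3flox, n = 3, and fm_neg_Gata3flox, n = 3). The other 4 came from wild-type mice (WT_tamoxifen, n = 2) and from mice with floxed Gata3 and an inducible Cre (Gata3KO_tamoxifen, n = 2), all given 3 injections of 5 mg tamoxifen. Total counts were 29459270 and 40639618 in fm_pos and 21434504 and 14450612 in fm_neg. They were 23371459, 29039911 and 44098274 in fm_pos_Gata3flox and 19589689, 21867082 and 16844805 in fm_neg_Gata3flox. They were 14529540 and 16770525 in WT_tamoxifen and 24576339 and 14676026 in Gata3KO_tamoxifen. The single-cell libraries were 1 of skin ILCs (sc_skin_ILC) and 1 each of dorsal skin ILCs taken 0 and 10 days after hair removal, which starts a new hair cycle. They had 10239594, 1171266 and 862679 counts in 4103, 553 and 443 cells kept, with medians of 2358, 1984 and 1811 counts per cell. The labels do not say whether replicates were separate animals, so p-values measure only the spread between these samples.

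Gata3, the transcription factor that ILC2s depend on (ENSMUSG00000015619, mm10 chromosome 2, 9857078 to 9890034, minus strand), was detected in every library, including all those labelled as floxed or knocked out. Its CPM was 164 and 303 in fm_pos, 381 and 504 in fm_neg, 154, 235 and 307 in fm_pos_Gata3flox, and 264, 430 and 442 in fm_neg_Gata3flox. It was 381 and 581 in WT_tamoxifen and 299 and 314 in Gata3KO_tamoxifen. The floxed label came with no called change in Gata3 counts: the log2 fold change was −0.01 ± 0.35 (SE) in reporter-positive cells and −0.22 ± 0.35 in reporter-negative cells. The tamoxifen knockout gave −0.65 ± 0.26. Gata3 passed the edgeR quasi-likelihood test in none of the 6 comparisons (Benjamini-Hochberg adjusted p from 0.230 to 1). Counts over the whole gene do not show whether the transcript was intact, and the files do not say which exons were floxed.

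**Figure D1:**
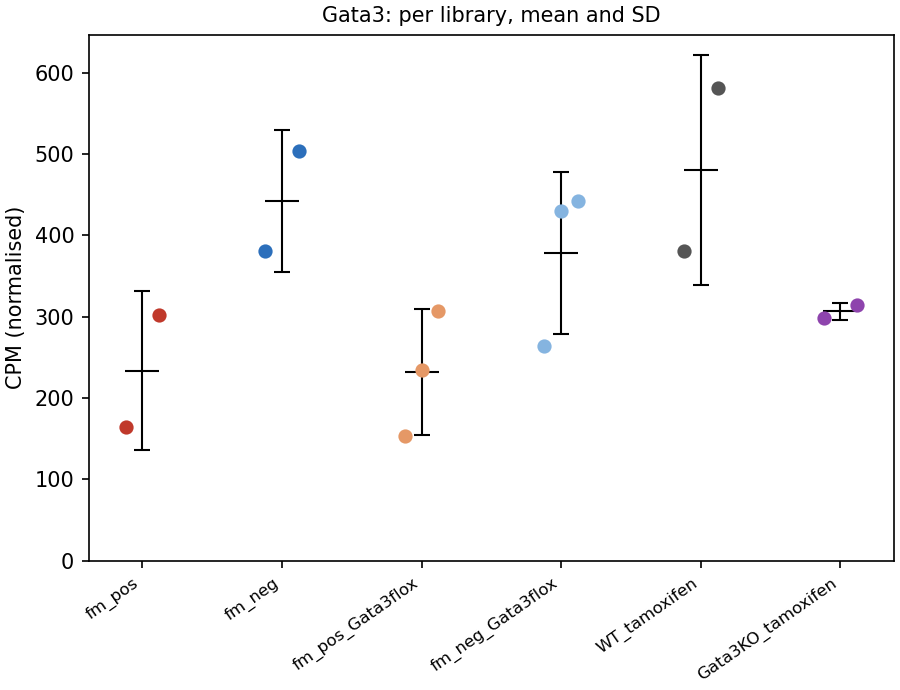
Normalised counts (y axis, CPM) of Gata3 in each library of the 6 bulk groups (x axis), with points for libraries, horizontal lines for the mean and error bars for the SD. Gata3 lies between 154 and 581 CPM in all libraries, and averages 233 CPM in fm_pos and 442 in fm_neg.

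Reporter-positive ILCs of intact mice differed from reporter-negative ones in several genes known from ILC2s and ILC3s. Il1rl1, the IL-33 receptor of ILC2s, averaged 6.21 ± 5.80 CPM (SD, n = 2) in fm_pos and 97.2 ± 15.9 (n = 2) in fm_neg and fell by 3.96 ± 0.68 (SE) on the log2 scale. The type 2 cytokine Il4 fell by 3.36 ± 0.40 (5.89 ± 1.49 against 60.3 ± 24.6 CPM). Csf2, which encodes the cytokine GM-CSF, fell by 3.21 ± 0.51 (30.1 ± 16.7 against 279 ± 182 CPM). The chemokine receptor Ccr6 of ILC3s rose by 1.61 ± 0.28 (646 ± 215 against 212 ± 35.6 CPM). The ion channel genes Tmem176a (305 ± 55.9 against 108 ± 60.9 CPM) and Tmem176b (464 ± 75.8 against 193 ± 35.7 CPM, log2 fold change 1.27 ± 0.21) rose as well. Tcf7, a transcription factor of early ILCs, rose by 1.18 ± 0.22 (191 ± 11.7 against 83.9 ± 2.01 CPM). These 7 genes had adjusted p from 0.00322 to 0.0475 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The fate-map comparison asked how cells with and without the mark differ, and in all it called 109 genes higher and 369 lower in fm_pos among 17456. The libraries of both groups overlapped for none of these 478 genes, and chance gives 33.3% of unselected genes with no overlap at 2 against 2. Calling genes from these same libraries favours those whose groups stand apart, so the lack of overlap is no separate support.

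Other called genes of fm_pos and fm_neg came from several groups. Ncr1, an activating receptor of NK cells and ILC1s, had 0 counts in fm_pos and was at least 172-fold lower, and the chemokine Ccl5 fell by 9.33 ± 0.92 on the log2 scale. The transcription inhibitor Id3 fell by 4.43 ± 0.45 (28.6 ± 6.93 against 617 ± 162 CPM). The growth factor gene Pdgfb rose by 4.15 ± 0.54 (38.8 ± 9.02 against 2.21 ± 1.60 CPM), Rab11fip4 by 5.20 ± 0.75 and Naif1 by 4.49 ± 0.95. Cd40lg, a costimulatory ligand, rose by 3.37 ± 0.70 with a wide spread (91.5 ± 89.8 against 8.83 ± 0.693 CPM). Zfp182 had 2 counts in fm_neg and a ratio of 457 (126 to 3777), and the chemokine Ccl3 had 1 count there and a ratio of 207 (36.9 to 8177). The immediate early gene Egr1 fell by 2.78 ± 0.49, the stress gene Ier3 by 2.32 ± 0.31 and the interferon response factor Irf1 by 2.25 ± 0.28. The T cell signalling gene Lat rose by 0.90 ± 0.20 and the receptor constant gene Trbc2 by 0.74 ± 0.15. Transcripts of keratinocytes and fibroblasts were far lower in fm_pos. The basal keratinocyte keratin Krt14 averaged 46.4 ± 32.3 CPM against 1701 ± 764 and Krt15 averaged 17 ± 7.65 against 474 ± 172 (log2 fold changes −5.20 ± 0.58 and −4.80 ± 0.51). The fibroblast proteoglycan Dcn averaged 71.0 ± 61.6 CPM against 5299.5 ± 1228 (−6.22 ± 0.68). The keratinocyte list summed to 4925 and 2624 CPM in the fm_neg libraries and 489 to 791 CPM in the other fate-map libraries, and the fibroblast list to 8599.5 and 6184 against 71.6 to 1102 CPM. The lipid carrier Apoe fell by 4.90 ± 0.26 and had the smallest adjusted p, 7.86e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The matrix and signalling genes Ccdc80, Dkk2, Wif1, Mmp3 and Cilp were at 0 counts in fm_pos and at least 1848-, 2041-, 3223-, 3176- and 3411-fold lower. Ebf1, a member of the B cell list, was at least 918-fold lower. Which cells its counts came from was not tested.

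Among the lists of ILC types, the ILC3 and type 17 list was higher in fm_pos (4 of 18 members rose and 0 fell, 5 and 0 adjusted over the list alone, median log2 fold change 0.90, or 1.09 with genes at their bound). Camera called it at adjusted p = 6.96e-05, and it had adjusted p = 0.0646 with an estimated correlation. The ILC2 list was lower by camera at adjusted p = 0.0290 (0 of 25 rose and 4 fell, 1 and 7 adjusted over the list alone, median −1.02, bounded −1.13). The ILC1 and NK list was lower at adjusted p = 0.0421 (2 rose and 2 fell of 23, 2 and 6 adjusted over the list alone, median −1.11). These had adjusted p = 0.470 and 0.626 with an estimated correlation. Signals to epithelium and hair follicle (1 rose and 4 fell of 26, median −1.06), lipid metabolism (0 and 1 of 18, −0.80), interferon response (0 and 1 of 16, −0.76) and immediate early and stress genes (0 and 4 of 18, −0.51) were lower by camera. Their adjusted p ran from 5.07e-06 to 0.0447, and adjusted p from 0.148 to 0.470 with an estimated correlation. Keratinocyte (0 rose and 5 fell of 14, median −1.95), fibroblast (0 and 4 of 10, −6.62), B cell (0 and 1 of 5, −9.82, bounded −6.70) and mast cell and basophil genes (0 and 0 of 9, −9.21, bounded −7.04) were lower by camera. Their adjusted p ran from 1.42e-14 to 0.0356, and adjusted p from 0.0646 to 0.470 with an estimated correlation. The T cell list was higher by camera (2 rose of 15, median 0.19, adjusted p = 0.0316, and adjusted p = 0.569 with an estimated correlation). The other lists did not pass camera: cell cycle (median −0.87), endothelial (−1.76), MHC class II (−0.79), myeloid (−0.35), survival and apoptosis (0.20), glycolysis (−0.11), progenitor (−0.06), melanocyte and Schwann cell (−1.53), sex-linked (0.47) and erythroid genes (adjusted p from 0.0734 to 0.905). Homing and residency (median 0.15, mean −0.93) and cytokine receptors (median 0.34, mean −0.00) had medians and means of opposite sign and did not pass camera (adjusted p = 0.250 and 0.409). Ribosomal protein (median −0.00) and mitochondrially encoded genes (median 0.01) changed sign between scaling methods and did not pass camera (adjusted p = 0.534 and 0.580).

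The count of called genes in the fate-map comparison was 2208 with DESeq2, 1324 with no filter on low counts, 250 with lane as a covariate, 29 when the libraries of both groups alone were fitted (0 higher and 29 lower), and 877 without fm_pos replicate 2 (198 higher and 679 lower). Without fm_neg replicates 1 and 2 the higher calls numbered 166 and 220. With fm_neg_Gata3flox as the negative side, an alternative chosen after the data were seen, it was 624, and Ccl3 (log2 fold change −2.25) and Egr1 (0.64) had the opposite sign. Of the named calls, 19 held without any 1 library, Il1rl1, Il4, Csf2, Id3, Ccl5, Ncr1, Krt14, Krt15, Dcn, Apoe and Pdgfb among them. The calls of Ccr6, Tmem176a, Trbc2 and Egr1 were lost without fm_pos replicate 1 or fm_neg replicate 1 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p up to 0.0733, 0.109, 0.129 and 0.0674), and that of Tmem176b without fm_neg replicate 1 (0.0536). Tcf7 and Ccl3 were lost without either fm_neg replicate (up to 0.0729 and 0.0816), and Cd40lg and Lat without fm_pos replicate 1 or either fm_neg replicate (0.200 and 0.140). Naif1 was lost without fm_pos replicate 2 or fm_neg replicate 1 (0.0734), Ebf1 without either fm_pos replicate or fm_neg replicate 1 (0.0767) and Cilp without either fm_pos replicate (0.0656). Mmp3 was lost without fm_pos replicate 1 or fm_neg replicate 2 (0.0567) and Wif1 without fm_pos replicate 1 (0.0522). Camera's calls of ILC3, immediate early, B cell, keratinocyte and fibroblast genes held without any 1 library. Those of ILC2, lipid metabolism and T cell genes were lost without fm_pos replicate 1 or either fm_neg replicate (camera adjusted p up to 0.201, 0.292 and 0.889). Those of ILC1 and NK and of interferon genes were lost without fm_pos replicate 2 or fm_neg replicate 2 (0.847 and 0.654). Signals to epithelium were lost without fm_neg replicate 1 (0.227), and mast cell genes without fm_pos replicate 1 or fm_neg replicate 1 (0.344).

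**Figure D2:**
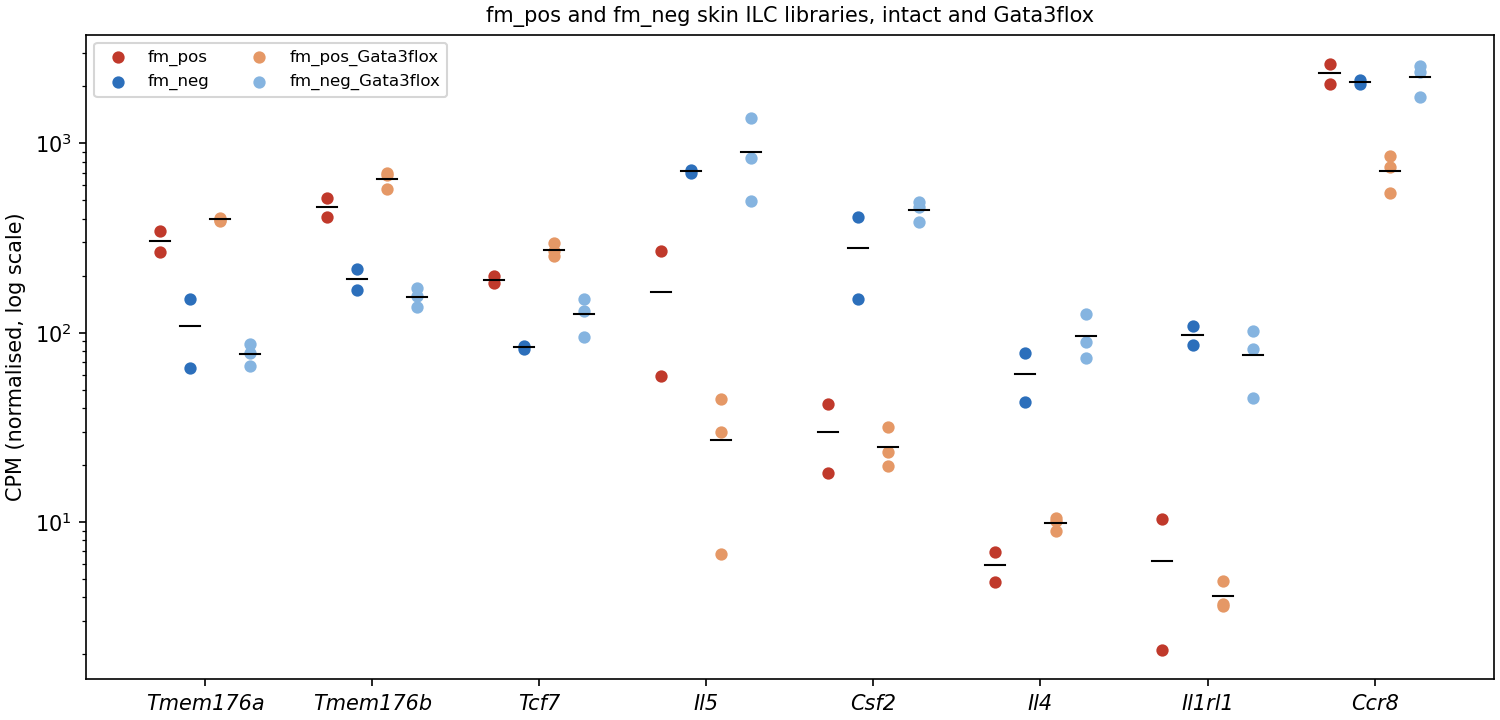
Normalised counts (y axis, CPM, log scale) of Tmem176a, Tmem176b, Tcf7, Il5, Csf2, Il4, Il1rl1 and Ccr8 in each library of the 4 fate-map groups (x axis), with black bars at the means. Il1rl1 averages 6.21 CPM in fm_pos and 97.2 in fm_neg, and 4.07 in fm_pos_Gata3flox and 76.2 in fm_neg_Gata3flox.

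**Figure D3:**
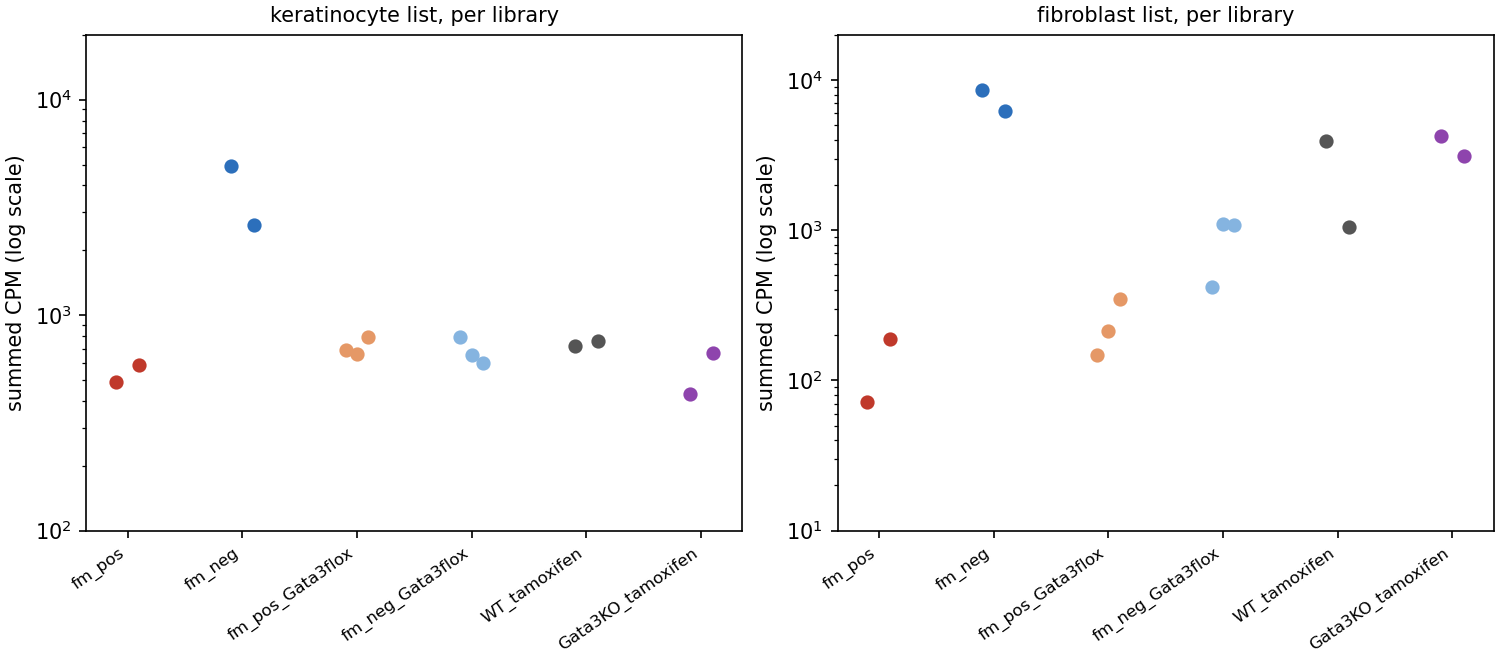
Summed counts (y axis, CPM, log scale) of the keratinocyte and fibroblast lists in each library of the 6 bulk groups (x axis). The fm_neg libraries lie at 4925 and 2624 CPM for keratinocyte genes, against 489 to 791 CPM in the other fate-map libraries.

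The same reporter comparison in mice labelled Gata3flox, with 3 libraries in each group, gave a fall in type 2 genes and a rise in ILC3 genes. The type 2 cytokine Il5 averaged 27.1 ± 19.1 CPM (SD, n = 3) in fm_pos_Gata3flox and 899 ± 433 (n = 3) in fm_neg_Gata3flox and fell by 5.05 ± 0.79 (SE) on the log2 scale. Il1rl1 fell by 4.23 ± 0.57 (4.07 ± 0.716 against 76.2 ± 28.6 CPM) and Csf2 fell by 4.16 ± 0.44 (24.9 ± 6.06 against 445 ± 56.0 CPM). Il4 fell by 3.28 ± 0.33 (9.90 ± 0.804 against 96.2 ± 27.0 CPM). Tmem176a rose by 2.36 ± 0.28 (397 ± 7.56 against 77.5 ± 10.3 CPM), Tmem176b by 2.07 ± 0.17 (652 ± 69.9 against 155 ± 18 CPM) and Tcf7 by 1.13 ± 0.18. The chemokine Ccl1 fell by 3.77 ± 0.43 and its receptor Ccr8, a skin-homing receptor, by 1.64 ± 0.20 (718 ± 159 against 2237 ± 420 CPM). The NK receptor Klrk1 fell by 1.47 ± 0.16, the costimulatory receptor Tnfrsf4 by 1.86 ± 0.31 and the transcription factor Ikzf2 by 1.40 ± 0.22. The lymphocyte receptor Slamf1 rose by 2.69 ± 0.42 (108 ± 6.80 against 16.8 ± 4.98 CPM), Lingo4 by 3.13 ± 0.52 and the inhibitory receptor Pdcd1, which encodes PD-1, by 1.89 ± 0.31. These genes had adjusted p from 0.00337 to 0.0433 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 17456 genes, 22 were called higher and 41 lower. The libraries of both groups overlapped for none of them, which the call itself favours, and chance gives 10% of unselected genes with no overlap at 3 against 3. Ccr6 (421 ± 22.6 against 225 ± 58.6 CPM, log2 fold change 0.90) and Dcn (88.9 ± 22.7 against 426 ± 132 CPM, −2.26) did not pass (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.200 and 0.0951).

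The ILC2 list was lower in fm_pos_Gata3flox (0 of 25 rose and 5 fell, 2 and 14 adjusted over the list alone, median log2 fold change −2.08, camera adjusted p = 1.90e-33). The ILC3 and type 17 list was higher (2 of 18 rose and 0 fell, 9 and 1 adjusted over the list alone, median 1.57, camera adjusted p = 6.83e-12). In all 6 comparisons these were the only camera calls that held with an estimated correlation, at adjusted p = 0.00789 and 0.00629. ILC1 and NK genes (0 rose and 1 fell of 23, median −0.93), signals to epithelium (0 and 2 of 26, −0.44), cytokine receptors (0 and 2 of 27, −0.24), fibroblast (0 and 0 of 10, −1.57), ribosomal protein (0 and 0 of 96, −0.33) and mitochondrially encoded genes (0 and 0 of 18, −0.26) were lower by camera. Their adjusted p ran from 3.58e-14 to 0.00871, and adjusted p from 0.166 to 0.451 with an estimated correlation. Endothelial genes were higher by camera with none of 8 members called (median 2.39, adjusted p = 0.000267, and adjusted p = 0.107 with an estimated correlation). The keratinocyte list had a median of −0.42 and did not pass camera (adjusted p = 0.700). The count of called genes was 419 with DESeq2, 321 with no filter, 113 at a mean CPM of at least 5, 233 with the libraries of both groups alone and 10 with lane as a covariate. It was 27, 2 (both higher) and 14 without fm_pos_Gata3flox replicates 1, 2 and 3 and 22, 11 and 9 without fm_neg_Gata3flox replicates 1, 2 and 3. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, Tmem176b held without any 1 library (adjusted p up to 0.0424). Il4 and Klrk1 were lost without fm_pos_Gata3flox replicate 2 (0.0549 and 0.0675), Csf2 without its replicate 2 or 3 (0.0549) and Ccl1 without replicate 2 or 3 of either group (0.0675). Ccr8 was lost without fm_pos_Gata3flox replicate 2 or fm_neg_Gata3flox replicate 2 or 3 (0.0833). Il1rl1 was lost without each library except fm_neg_Gata3flox replicate 1 (0.106), and Tmem176a without each except fm_pos_Gata3flox replicate 1 (0.0833). Il5, Tcf7, Slamf1, Lingo4, Pdcd1, Ikzf2 and Tnfrsf4 were lost without each of the 6 libraries (0.0567 to 0.237). Camera's call of mitochondrial genes was lost without fm_pos_Gata3flox replicate 3 (camera adjusted p = 0.167), and its other 8 calls held without any 1 library.

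The fate-map comparisons of intact and Gata3flox-labelled mice shared 6 genes called higher and 10 called lower in reporter-positive cells, where chance gives 0.137 and 0.867 (Fisher's exact test, 2-sided, p = 3.55e-09 and 9.87e-09). In opposite directions 1 gene was called. Genes are not independent and both comparisons came from 1 fit, so these p-values are descriptive. Of the 478 genes called in intact mice, 335 (70.1%) had the same sign in Gata3flox-labelled mice, against 51.7% of all genes. Across all genes, which are not independent replicates, the log2 fold changes of both comparisons had Pearson's r = 0.133 and Spearman's rho = 0.142.

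Reporter-positive ILCs of mice labelled Gata3flox were set against those of intact mice to ask how that population differs with the floxed label, where Gata3 counts showed no called difference. The IL-25 receptor gene Il17rb averaged 2.93 ± 1.30 CPM (SD, n = 3) in fm_pos_Gata3flox and 83.2 ± 29.1 (n = 2) in fm_pos and fell by 4.83 ± 0.53 (SE) on the log2 scale. The IL-9 receptor gene Il9r fell by 2.83 ± 0.42 (11.5 ± 5.33 against 81.5 ± 10.9 CPM). Ccr8 fell by 1.71 ± 0.21 (718 ± 159 against 2349 ± 393 CPM), the lipid enzyme gene Lpcat2 by 2.39 ± 0.33, the IL-6 receptor gene Il6ra by 2.49 ± 0.33, and Itgae, the integrin CD103 of tissue-resident lymphocytes, by 1.63 ± 0.25. Bmp2, a signal to hair follicles, fell by 2.05 ± 0.40 (25.7 ± 10.8 against 107 ± 50.3 CPM). Among genes that rose, the signalling adaptor Tyrobp rose by 6.65 ± 0.71 (194 ± 67.9 against 1.95 ± 1.33 CPM) and the granzyme gene Gzmc by 5.32 ± 0.65 (894 ± 459 against 22.4 ± 2.68 CPM). The chemokine receptor Cxcr3 rose by 2.68 ± 0.37 and Ccl5 by 11.25 ± 0.95 (219.5 ± 135 CPM, against 6 counts in fm_pos). Ncr1 and the NK adaptor gene Sh2d1b1 had 0 counts in fm_pos and were at least 386- and 600-fold higher. Cd40lg fell by 6.45 ± 0.68 (1.03 ± 0.306 against 91.5 ± 89.8 CPM), Paqr4 fell by 3.25 ± 0.65 and Gnaz fell by 3.19 ± 0.64. The stress factor gene Atf3 fell by 1.62 ± 0.30 and Jund by 1.48 ± 0.24, and the ribosomal gene Rps13 rose by 0.83 ± 0.15. Plek, Bend4, the mitotic genes Spc24 and Ccnb1, and the endothelial junction gene Cldn5 were at 0 counts in fm_pos and at least 537-, 427-, 342-, 237- and 252-fold higher. The collagen gene Col3a1 and the growth factor gene Igf1 had 1 count in fm_pos and ratios of 1194 (214 to 47195) and 600.4 (107 to 23745). Many of these genes shifted the same way from fm_neg to fm_neg_Gata3flox, with no overlap of libraries. Besides Tyrobp and Il17rb, these were Ncr1, Sh2d1b1, Gzmc, Cxcr3, Ccl5, Plek, Bend4, Rps13, Il6ra, Itgae, Bmp2, Atf3, Jund and Paqr4. Ncr1 went from 6.08 and 9.18 to 75.4, 38.4 and 25.1 CPM. Tyrobp went from 33.0 and 91.4 to 454, 428 and 263 CPM, and Il17rb from 37.2 and 53.1 to 8.40, 10.2 and 18.65 CPM. Cd40lg, Col3a1, Igf1 and Cldn5 went the other way. The reporter-negative libraries overlapped for Ccr8, Il9r, Lpcat2, Gnaz, Spc24 and Ccnb1. A change in both populations cannot be told apart from a difference between the sets of libraries.

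Between these reporter-positive groups 193 genes were called higher and 73 lower of 17456, with adjusted p down to 0.00159 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The libraries of both groups overlapped for none of them, which the call itself favours (chance gives 20% of unselected genes at 3 against 2), and 81 of the higher genes had 0 counts in fm_pos. The median of all genes lay at 0.18 with TMM, 0.15 with RLE and 0.25 with upper-quartile factors. More genes were detected in the Gata3flox-labelled libraries (17730 to 18974) than in the intact fate-map libraries (14525 to 15410). By camera the ILC2 list (0 of 25 rose and 4 fell, 2 and 8 adjusted over the list alone, median −0.61), cytokine receptors (0 and 3 of 27, −0.42), glycolysis (0 and 0 of 15, −0.44) and immediate early genes (0 and 2 of 18, −0.06 with TMM but 0.01 with upper-quartile factors) were lower. Camera's adjusted p ran from 1.22e-06 to 0.00995, and adjusted p from 0.253 to 0.449 with an estimated correlation. ILC1 and NK genes (5 rose and 1 fell of 23, median 1.64), cell cycle (1 and 0 of 24, 1.12), interferon response (0 and 0 of 16, 6 and 0 adjusted over the list alone, 1.51), MHC class II (0 and 0 of 7, 5 and 0 adjusted over the list alone, 1.46) and ribosomal protein genes (1 and 0 of 96, 0.50) were higher. Camera's adjusted p ran from 1.16e-06 to 0.0114, and adjusted p from 0.260 to 0.462 with an estimated correlation. Genes of other cell types were higher too: B cell (0 of 5 called, median 8.18, bounded 4.79), myeloid (1 of 13, 5.27, bounded 3.11), endothelial (1 of 8, 6.73, bounded 5.89), fibroblast (1 of 10, 3.14, bounded 2.47) and keratinocyte genes (0 of 14, 0.77). Camera's adjusted p ran from 0.000828 to 0.0270, and adjusted p from 0.253 to 0.435 with an estimated correlation. ILC3 genes (median −0.04 with TMM, 0.04 with upper-quartile factors, mean 0.99) and homing genes (median −0.15, mean 0.80) did not pass camera (adjusted p = 0.142 and 0.159). The count was 1919 with DESeq2, 974 with no filter and 133 with lane as a covariate, and it was 0 with edgeR on the libraries of both groups alone (2818 at an unadjusted p under 0.05). It was 430 and 489 without fm_pos replicates 1 and 2 and 92 and 66 without fm_pos_Gata3flox replicates 1 and 2. Without fm_pos_Gata3flox replicate 3 the lower calls numbered 125.

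Single libraries also decided some calls between the reporter-positive groups. Tyrobp, Gzmc, Cxcr3, Ccl5, Ncr1, Il17rb, Ccr8, Lpcat2, Il6ra, Cd40lg, Plek, Bend4, Col3a1 and Igf1 held without any 1 library. Il9r and Sh2d1b1 were lost without fm_pos_Gata3flox replicate 2 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0651 and 0.0535), and Itgae, Ccnb1 and Cldn5 without its replicate 1 or 2 (up to 0.0622, 0.0712 and 0.0535). Spc24 was lost without either fm_pos replicate or fm_pos_Gata3flox replicate 2, Bmp2 and Atf3 without fm_pos replicate 2 or fm_pos_Gata3flox replicate 1 or 2, and Jund without fm_pos replicate 1 or fm_pos_Gata3flox replicate 1 or 2 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p up to 0.0667, 0.129, 0.118 and 0.0911). Gnaz and Rps13 were lost without 4 of the 5 libraries and Paqr4 without each of the 5 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p up to 0.145, 0.103 and 0.138). Camera's calls of ILC2, cytokine receptor, interferon, MHC class II, B cell, endothelial and ribosomal genes held without any 1 library. The ILC1 and NK call was lost without fm_pos replicate 2 (adjusted p = 0.0819), fibroblast without fm_pos replicate 1 (0.298), myeloid without either fm_pos replicate (0.0611), and cell cycle without fm_pos replicate 1 or fm_pos_Gata3flox replicate 1 (0.446). Glycolysis and immediate early genes were lost without fm_pos replicate 2 or fm_pos_Gata3flox replicate 1 (adjusted p up to 0.257 and 0.280), and keratinocyte genes without fm_pos replicate 2 or fm_pos_Gata3flox replicate 3 (0.257).

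Reporter-negative ILCs of mice labelled Gata3flox were compared with those of intact mice in the same way, again with no called difference in Gata3. The death ligand gene Fasl averaged 122 ± 25.1 CPM (SD, n = 3) in fm_neg_Gata3flox and 21.3 ± 2.43 (n = 2) in fm_neg and rose by 2.52 ± 0.29 (SE) on the log2 scale. Gzmc rose by 3.44 ± 0.59 (1384 ± 665 against 128 ± 72.1 CPM). Pdgfb rose by 3.64 ± 0.51 and Ms4a4c by 6.46 ± 1.07. The ribosomal gene Rps9 rose by 0.82 ± 0.14, Rps4x by 0.99 ± 0.17 and the mitochondrial gene mt-Co1 by 0.75 ± 0.14 (8464 ± 243 against 5034 ± 853 CPM). Ly6g6c had 0 counts in fm_neg and was at least 357-fold higher. Ccl3 and Zfp930 had 1 count there and ratios of 1108 (199 to 43805) and 956 (171 to 37774). Keratinocyte and fibroblast genes were lower. Krt14 fell by 4.67 ± 0.48 (67.0 ± 14.6 against 1701 ± 764 CPM), Krt15 by 4.24 ± 0.42, and Dcn by 3.64 ± 0.51 (426 ± 132 against 5299.5 ± 1228 CPM). Igfbp3, a carrier of insulin-like growth factors, fell by 6.09 ± 0.62. Angptl7 fell by 5.40 ± 0.89, Angptl2 by 6.65 ± 1.25 and Igf1 by 3.79 ± 0.73. Pi16 and Ptgfr had 1 count in fm_neg_Gata3flox and ratios of 0.000648 (1.64e-05 to 0.00362) and 0.000639 (1.62e-05 to 0.00357). Egr1 fell by 3.42 ± 0.43, Ier3 by 2.06 ± 0.26, Id3 by 2.53 ± 0.36 and Pdcd1 by 1.71 ± 0.34. The ILC2 list did not pass camera (0 of 25 called, median 0.06 with TMM and −0.01 with RLE, adjusted p = 0.749).

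Between the reporter-negative groups 104 genes were called higher and 129 lower of 17456, with adjusted p down to 0.00186 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The libraries overlapped for none, which the call itself favours (chance gives 20% of unselected genes at 3 against 2). The share of higher calls depended on scaling: 44.6% with TMM, 28.8% with RLE (53 higher and 131 lower) and 62.8% with upper-quartile factors (186 and 110), with the median of all genes at 0.07, 0 and 0.20. By camera the ILC1 and NK list (4 rose and 0 fell of 23, 11 and 0 adjusted over the list alone, median 1.17), ribosomal protein (18 and 0 of 96, 74 and 0 adjusted over the list alone, 0.83), mitochondrially encoded (1 and 0 of 18, 0.65) and erythroid genes (0 and 0 of 5, 9.19, bounded 5.13) were higher. Camera's adjusted p ran from 1.61e-29 to 0.0194, and adjusted p from 0.249 to 0.491 with an estimated correlation. Glycolysis (0 rose and 0 fell of 15, 0 and 5 adjusted over the list alone, median −0.73), immediate early (0 and 4 of 18, −0.96), keratinocyte (0 and 4 of 14, −1.46) and fibroblast genes (0 and 1 of 10, −2.60) were lower. Camera's adjusted p ran from 1.42e-11 to 1.25e-05, and adjusted p = 0.249 with an estimated correlation for each. The count was 1584 with DESeq2, 893 with no filter, 425 at a mean CPM of at least 5, 367 with the libraries of both groups alone and 77 with lane as a covariate. It was 190 without fm_neg replicate 2, where 127 higher and 63 lower turned the balance, 102 without fm_neg replicate 1, and 17, 5 and 18 without fm_neg_Gata3flox replicates 1, 2 and 3. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, Krt15, Igfbp3, Ly6g6c and Zfp930 held without any 1 library (adjusted p up to 0.0484). Krt14 and Fasl were lost without fm_neg_Gata3flox replicate 2 (0.0518) and Egr1 without its replicate 2 or 3 (0.0767). Ier3, Dcn, Pdgfb and Ms4a4c were lost without each fm_neg_Gata3flox replicate (up to 0.125). Gzmc, Id3, mt-Co1 and Ptgfr were lost without each of these or fm_neg replicate 1, and Pdcd1 without each of these or fm_neg replicate 2 (up to 0.164). Angptl7 was lost without fm_neg replicate 2 or fm_neg_Gata3flox replicate 1 or 2 (0.105). Ccl3, Igf1, Pi16, Rps9, Rps4x and Angptl2 were lost without each of the 5 libraries (highest values from 0.0918 to 0.164).

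Camera's calls of ILC1 and NK, immediate early, fibroblast, ribosomal and mitochondrial genes between the reporter-negative groups held without any 1 library. Glycolysis was lost without fm_neg replicate 2 (adjusted p = 0.0569), keratinocyte genes without fm_neg replicate 1 (0.251) and erythroid genes without either (0.205).

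Both Gata3flox-labelled populations shared 17 genes called higher and 4 called lower against their intact counterparts, where chance gives 1.15 and 0.539 (Fisher's exact test, 2-sided, p = 1.60e-15 and 0.00209), and 13 genes were called in opposite directions. No chance value was computed for the opposite calls. Genes are not independent and both comparisons came from 1 fit, so these p-values are descriptive. They cannot tell a shared change from genes that are easier to call in both. Of the 266 genes called in reporter-positive cells, 143 (53.8%) had the same sign in reporter-negative cells, below the 57.8% of all genes.

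The interaction asked whether the floxed label went with a different change in reporter-positive than in reporter-negative cells, and it called 144 genes higher and 32 lower of 17456. Of these, 67 had 0 counts in fm_pos. Igf1 averaged 64.6 ± 17.4 CPM (SD, n = 2) in fm_neg and 4.66 ± 3.19 (n = 3) in fm_neg_Gata3flox, but had 1 count in fm_pos and 9.54 ± 6.31 CPM (n = 3) in fm_pos_Gata3flox. Gas6, a ligand of TAM receptors, went from 65.4 ± 19.3 to 3.92 ± 0.215 CPM in reporter-negative cells and from 0 counts to 3.65 ± 2.24 CPM in reporter-positive cells. Tgfbi, Ptn and Tm4sf1 had the same pattern, with 0, 0 and 1 counts in fm_pos. In the other direction, Ly6g6c went from 0 counts to 29.8 ± 13.4 CPM in reporter-negative cells and from 11.8 ± 6.66 to 14.3 ± 1.995 CPM in reporter-positive cells. Ccl3, Zfp930, Zfp182 and Ccdc125 also had 1 or 2 counts in fm_neg. The fitted log2 interactions of these 10 genes, 12.79 to 14.08 for the higher and −12.32 to −8.17 for the lower, depend on the prior count. Gata3 (0.21 ± 0.50 SE) did not pass (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.971). The ILC2 list had a lower interaction (median −0.99, camera adjusted p = 0.000112, and adjusted p = 0.259 with an estimated correlation). Camera called 12 lists in all, and none held with an estimated correlation. Among them the fibroblast (median 5.16), endothelial (4.18) and keratinocyte lists (1.89) had higher interactions. The count of called genes was 1158 with DESeq2, 773 with no filter and 73 with lane as a covariate. It was 26 (25 higher and 1 lower) with replicate number as a block. Gas6, Igf1, Ly6g6c and Zfp930 held without any 1 library. Tgfbi was lost without fm_pos_Gata3flox replicate 3 or fm_neg_Gata3flox replicate 1 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p up to 0.0663), and Ptn without fm_pos replicate 1 or each fm_neg_Gata3flox replicate (0.0943). Zfp182 was lost without each fm_pos_Gata3flox replicate or fm_neg_Gata3flox replicate 1 or 2 (0.0796). Tm4sf1 was lost without each fm_pos replicate, fm_pos_Gata3flox replicate 2 or 3, or fm_neg_Gata3flox replicate 1 or 2 (0.0857). Ccl3 and Ccdc125 were lost without each library except those of fm_pos (0.115 and 0.107). The count was 330 and 504 without fm_pos replicates 1 and 2, 89, 81 and 78 without fm_pos_Gata3flox replicates 1, 2 and 3, and 63, 54 and 71 without fm_neg_Gata3flox replicates 1, 2 and 3. Without fm_neg replicates 1 and 2 the lower calls numbered 84 and 78.

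Libraries labelled as tamoxifen-induced Gata3 knockout were compared with tamoxifen-treated wild type, and no gene passed the test, Gata3 included. Gata3 averaged 307 ± 10.6 CPM (SD, n = 2) in Gata3KO_tamoxifen and 481 ± 141 (n = 2) in WT_tamoxifen. Il1rl1 stood at 29.2 ± 3.51 against 77.2 ± 1.42 CPM (log2 fold change −1.40 ± 0.27 SE) and the ILC2 receptor gene Klrg1 at 12.9 ± 2.14 against 48.1 ± 16.2 CPM (−1.89 ± 0.43). The neuropeptide gene Calca stood at 128 ± 19.6 against 452 ± 278 CPM (−1.82 ± 0.48). The type 17 cytokine Il17a stood at 76.6 ± 15.7 against 183 ± 57.7 CPM (−1.26 ± 0.32) and Il22 at 8.06 ± 7.65 against 189 ± 172 CPM (−4.57 ± 1.14). The IL-23 receptor gene Il23r stood at 234 ± 13.7 against 83.0 ± 27.9 CPM. The bone and epithelial signal Tnfsf11 stood at 67.2 ± 11.2 against 16.5 ± 3.58 CPM (2.03 ± 0.35). The antigen presentation gene H2-Eb1 stood at 23.3 ± 1.80 against 72.1 ± 1.99 CPM (−1.63 ± 0.28), Cd74 at 311 ± 52.2 against 817 ± 173 CPM (−1.39 ± 0.25) and the glycolysis gene Tpi1 at 78.8 ± 3.54 against 269 ± 72.6 CPM (−1.77 ± 0.27). Tbx21, the transcription factor of ILC1s, had 0 counts in the knockout, at least 63.0-fold lower. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 13272 genes passed (smallest adjusted p = 0.585), with 915 at an unadjusted p under 0.05, 200 called by DESeq2 and 6 with no filter on low counts.

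As lists, MHC class II genes (0 of 6 called, 0 and 5 adjusted over the list alone, median −1.79), ILC2 genes (0 of 22, −0.77), cell cycle (0 of 24, −0.82), glycolysis (0 of 15, −0.58), signals to epithelium (0 of 24, −0.31) and immediate early genes (0 of 18, −0.26) were lower in the knockout. Camera's adjusted p ran from 3.94e-13 to 0.00803, and adjusted p from 0.530 to 0.566 with an estimated correlation. Interferon response (0 of 12, median 0.99) and sex-linked genes (0 of 4, 1.35) were higher by camera (adjusted p = 0.0285 and 0.0145, and adjusted p = 0.548 and 0.566 with an estimated correlation). ILC3 genes (median −0.17) and ILC1 and NK genes (median −1.04) did not pass camera (adjusted p = 0.876 and 0.0959). The MHC class II call held without any 1 library (adjusted p up to 0.0235). The ILC2 call was lost without WT_tamoxifen replicate 2 or Gata3KO_tamoxifen replicate 1 and cell cycle without WT_tamoxifen replicate 2 (camera adjusted p up to 0.316 for each). Glycolysis was lost without WT_tamoxifen replicate 2 (0.160), and signals to epithelium and interferon genes without WT_tamoxifen replicate 2 or either knockout replicate (0.386 and 0.316). Immediate early genes were lost without WT_tamoxifen replicate 1 or Gata3KO_tamoxifen replicate 2 (0.307) and sex-linked genes without WT_tamoxifen replicate 1 or either knockout replicate (0.519). WT_tamoxifen replicate 1 had 1469 counts of Xist and 0 of the Y-linked Ddx3y, unlike the other 3 tamoxifen libraries, so sex differed between the wild-type libraries. No gene could be shared with the calls in fm_pos_Gata3flox against fm_pos: of those 245 calls that were tested in both sets, 117 (47.8%) had the same sign here, against 49.1% of all genes.

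The single-cell library of skin ILCs asked which subgroups the sorted cells hold. Gata3 stood at 1698 CPM over its 4103 cells, with Il5 at 1201, Areg, an epithelial growth factor, at 416, Il13 at 281 and Csf2 at 133 CPM, and Il17a and Il22 at 17.3 and 48.4 CPM. Its largest clusters, cluster 2 (1862 cells, 45.4%) and cluster 3 (1327 cells, 32.3%), were left unnamed and had Gata3 at 1835 and 2065 CPM. The former was led by the costimulatory receptor gene Tnfrsf9 and the latter by the activation genes Nfkbid and Tnfsf9. Cluster 5 (558 cells, 13.6%), led by the heat shock gene Hspa1a, had Gata3 at 859 CPM. Cluster 4 (285 cells, 6.95%) was led by the T cell receptor complex genes Cd3e and Cd3d with Trdc, met the T cell and the ILC3 lists and was left unnamed. It had Il17a at 113, Il17f at 103, Il22 at 156 and Gata3 at 521.1 CPM. Small clusters were myeloid-like (57 cells, 1.39%) and B cell-like (14 cells, 0.341%). A Gata3 count appeared in 68.4% of myeloid-like and 50% of B cell-like cells, types that should lack it, at 1277 and 579.7 CPM. A Gata3 count in a cell thus does not by itself show expression there. Doublets that passed the filter were not ruled out: 3 of 4444 cells had been predicted as doublets. Il1rl1 and Lpcat2 were raised in the myeloid-like cluster as well. The 6 clusters of this library became 9 with doublets kept, with at least 500 genes per cell or with readout genes kept, 5 at resolution 0.3 and 13 at resolution 1.0.

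Dorsal skin ILCs fell into 3 clusters with different cytokine levels. Cluster 0 was ILC2-like, led by Npnt, Tff1, Il1r2 and Il1rl1, and held 179 cells on day 0 (32.4%, 28.5 to 36.4) and 185 cells on day 10 (41.8%, 37.1 to 46.5). Its Il5 stood at 3760.1 CPM on day 0, against 553 in cluster 1, led by Qpct, Cstb and Cx3cr1, and 2174 in cluster 2, led by the immediate early genes Nfkbid, Zfp36 and Egr1. On day 10 Il5 stood at 2508, 781 and 666 CPM in clusters 0, 1 and 2. Gata3 stood at 1760.2, 1105 and 1275 CPM in clusters 0, 1 and 2 on day 0, and at 1520.5, 1069 and 1518 CPM on day 10. At resolution 0.3 all dorsal cells fell into 1 cluster and at resolution 1.0 into 9, so the number of clusters follows the setting.

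**Figure D4:**
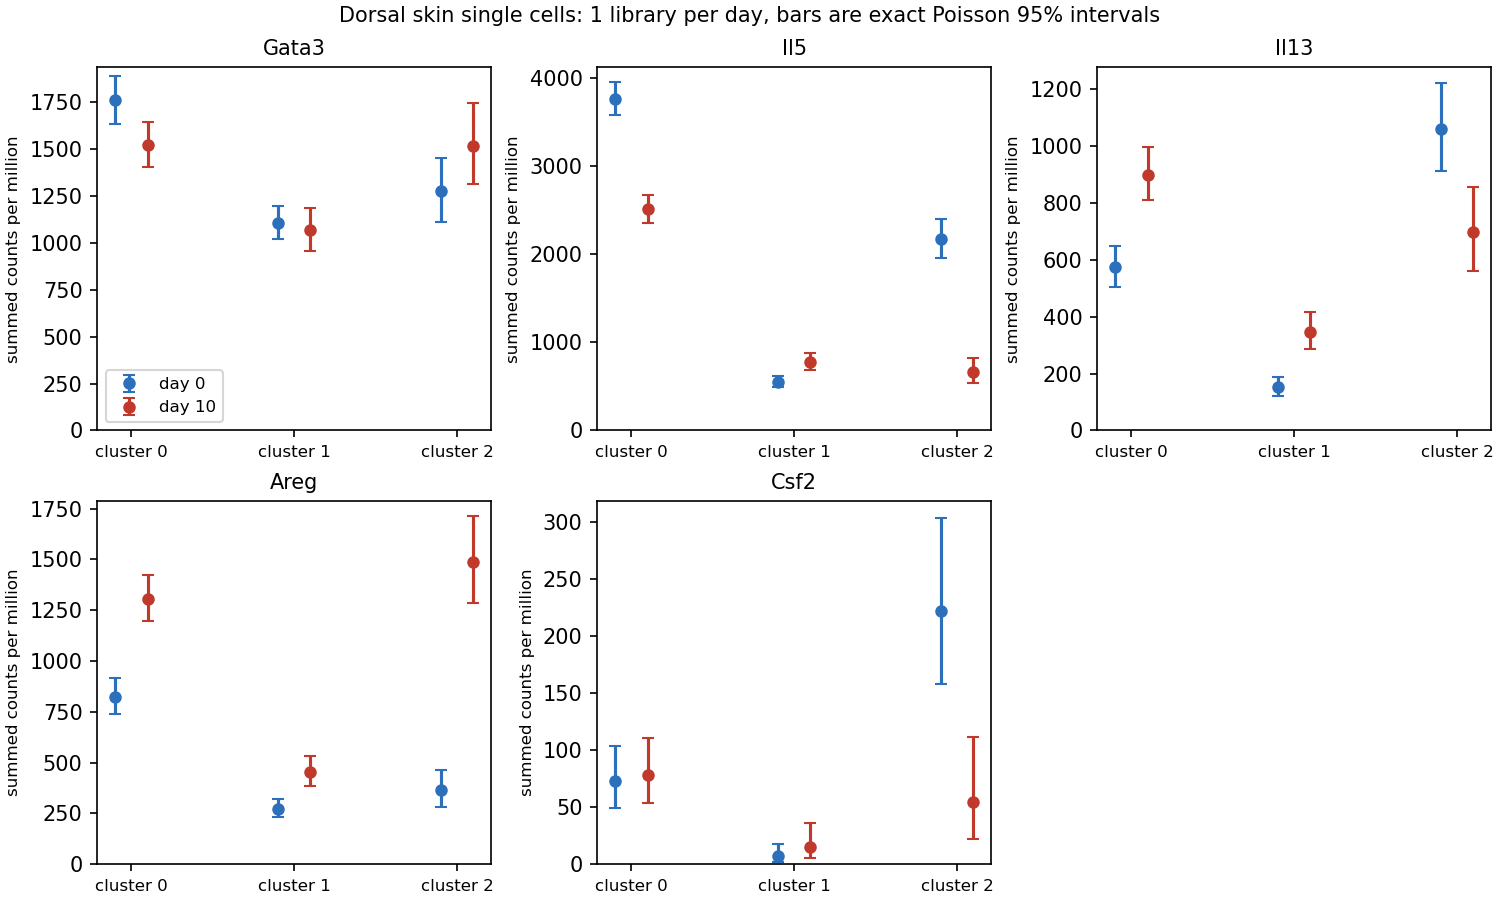
Summed counts (y axes, CPM) of Gata3, Il5, Il13, Areg and Csf2 in the 3 dorsal clusters (x axes) on day 0 (blue) and day 10 (red), with exact Poisson 95% counting intervals. Il5 on day 0 stands at 3760.1 CPM in cluster 0 and 553 CPM in cluster 1.

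Between day 10 and day 0 after depilation, over all dorsal cells, Areg had a higher level (1011 against 488 CPM, ratio 2.07, 1.86 to 2.31), as did the type 2 cytokine Il13 (ratio 1.49, 1.32 to 1.69), Il17a (1.51, 1.06 to 2.15) and Il1rl1 (2.83, 2.37 to 3.39). Il5 (0.805, 0.752 to 0.861) and Il17f (0.384, 0.190 to 0.722) had lower levels on day 10. On day 0 and day 10 the counts were only 64 and 71 for Il17a and 46 and 13 for Il17f. Their intervals leave out the spread between cells. Il5 went the other way in cluster 1, from 553 (493 to 617) to 781 (688 to 883) CPM. Il13 went the other way in cluster 2, where it fell, with the levels given under the other observations. The ratios of Gata3 (0.986, 0.913 to 1.06), Csf2 (0.807, 0.543 to 1.19), Tbx21 (1.55, 0.492 to 5.03) and Ifng (0.905, 0.321 to 2.41) had intervals that included 1. Il22 had 0 counts on both days, which allows up to 2.56 and 3.48 CPM (3 counts of the total). Of 3362 genes with enough counts, 20 were higher and 16 lower past the size set for naming. Apart from the Y-linked Ddx3y (246) and from Il1rl1, the highest were the opioid peptide gene Penk (160.2, 28.2 to 6381, with 1 count on day 0), the chemokine Cxcl2 (3.18, 2.24 to 4.57), Lilr4b (3.12), Atp10d (2.84), the adhesion molecule gene Icam1 (2.70, 2.03 to 3.60), Socs2 (2.65), Slc12a2 (2.59) and Cd3g (2.39). Apart from the sex-linked Xist (0.104), the lowest were Ppp2r3a (0.0745, 0.0428 to 0.121), Enpp2 (0.268), the chemokine receptor gene Cx3cr1 (0.322, 0.203 to 0.493), Ramp1 (0.411), Ppt1 (0.432), Eno1b (0.441), Gnb4 (0.443), Plrg1 (0.453) and Dnajc10 (0.460). Within the ILC2-like cluster alone the ratios were 1.58 for Areg, 0.667 for Il5 and 0.864 for Gata3, 1.08 for both Il17a and Csf2, 2.27 for Il1rl1, 4.33 for Socs2 and 0.293 for Dnajc10. With cells thinned to equal counts the ratios were 5.15 for Slc12a2, 0.0404 for Ppp2r3a and 0.302 for Eno1b. Of the lists, survival and apoptosis (median log2 ratio 0.37), glycolysis (0.29), signals to epithelium (0.32) and ribosomal protein genes (0.10) lay at or above the 99.82nd percentile of matched random lists, as did the sex-linked list (5.50). Sex-linked counts differed with day: Xist and Ddx3y had 899 and 2 counts on day 0 and 69 and 363 on day 10. Day 10 thus held counts of both, and whether it mixed cells of both sexes was not examined. With 1 library per day the day and the preparation cannot be separated, and sex was not separated from them.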

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

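The tests of abundant transcripts, of a difference shared by both sorted populations, of gene detection and of cell depth were chosen only after the result was seen.

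The interaction of reporter status and floxed label was tested directly, and 176 genes differed in their change between reporter-positive and reporter-negative cells. Of these, 67 had 0 counts in fm_pos. With replicate number as a block the count was 26, with 25 higher and 1 lower. Among the named genes, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p of the interaction was 0.0326 for Ptn, 0.00361 for Gas6, 0.0206 for Tgfbi, 0.0388 for Tm4sf1 and 0.00534 for Igf1, which had higher interactions. It was 0.00606 for Ly6g6c, 0.0389 for Ccdc125, 0.0416 for Ccl3, 0.00766 for Zfp930 and 0.0260 for Zfp182, which had lower ones. Among lists, camera gave an adjusted p of 0.000112 for ILC2 (median −0.99), 0.0105 for cytokine receptors (−0.28), 0.0430 for T cell (−0.54) and 6.62e-06 for ribosomal protein genes (−0.32). It gave 0.00406 for lipid metabolism (median 0.83), 0.0184 for interferon response (1.10), 0.00221 for immediate early (0.34), 0.0184 for MHC class II (1.53), 0.000112 for B cell, 1.49e-08 for keratinocyte (1.89), 3.19e-11 for fibroblast (5.16) and 0.000558 for endothelial genes (4.18). With an estimated correlation none of these 12 lists passed (camera, adjusted p from 0.0963 to 0.590). Keratinocyte and fibroblast genes were high in the intact fm_neg libraries, as described next. Their interaction cannot be told apart from RNA or cells of skin origin in those libraries. Camera's call of cytokine receptors was lost without fm_pos replicate 2 or fm_neg replicate 1 (adjusted p up to 0.175) and that of lipid metabolism without fm_pos replicate 1 or either fm_neg replicate (0.368). Interferon response was lost without fm_pos replicate 2, fm_neg replicate 2 or fm_neg_Gata3flox replicate 3 (0.557) and immediate early genes without fm_pos replicate 1 or fm_neg replicate 1 (0.203). MHC class II was lost without fm_neg replicate 2 or fm_pos_Gata3flox replicate 2 (0.0942), and T cell genes without each library except fm_pos replicate 2, fm_pos_Gata3flox replicate 1 and fm_neg_Gata3flox replicate 3 (0.825).

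Keratinocyte and fibroblast genes were higher in the intact fm_neg libraries than in any other fate-map group, with summed fibroblast CPM of 8599.5 and 6184 against 71.6 to 1102, where the CD90-positive gate should remove keratinocytes but need not remove dermal fibroblasts, which can carry CD90. If this were a property of all reporter-negative cells, the 369 genes called lower in fm_pos should be lower in the Gata3flox-labelled libraries too, but as a set their median log2 fold change there was −0.49, against −7.53 in intact mice with genes at their bound, although choosing extreme genes also shrinks a median. Fibroblast genes went partly with such a property: in the Gata3flox-labelled libraries their list was lower in reporter-positive cells (median −1.57, camera adjusted p = 0.000260, and adjusted p = 0.409 with an estimated correlation), with summed CPM of 147, 212.5 and 351 against 421, 1102 and 1091. Of the 24 tested keratinocyte and fibroblast members, 58.3% lay above the other 8 fate-map libraries in both fm_neg libraries, which restates the pattern and does not separate the explanations. By the median of the 369 genes, RNA or cells of skin origin carried into the fm_neg sort may account for part of the lower calls in intact mice, while a difference in fibroblast genes between reporter-positive and reporter-negative cells, or between genotypes, stays open.

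The ILC2 list was lower in fm_pos_Gata3flox than in fm_pos (median −0.61, camera adjusted p = 1.22e-06, and adjusted p = 0.253 with an estimated correlation), with no called difference in Gata3 counts. Poorer detection in fm_pos_Gata3flox was argued against, since 89.6% of tested genes were detected per fm_pos_Gata3flox library and 74.6% per fm_pos library. Whether the fewer genes detected in fm_pos raised the scaled counts of its ILC2 genes was not tested. A difference between the 2 sets of libraries that has nothing to do with the floxed allele could not be told apart: the same list had a median of 0.0643 in reporter-negative cells, which was −0.01 with RLE factors, and the interaction did not pass with an estimated correlation (camera, adjusted p = 0.259). An effect of the floxed allele on Gata3 function without a loss of counts stays open and was not tested.

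A tdtomato transcript, from a red fluorescent reporter that the comparisons did not use, was counted in 113 of 553 dorsal cells on day 0 (20.4%, exact 95% interval 17.1 to 24.04) and 28 of 443 on day 10 (6.32%, 4.24 to 9.01). Depth alone was argued against on day 0, since in clusters made without the tdtomato row and with cells thinned to equal counts the share was 19.2% (14.6 to 24.4) in cluster 1 and 5.23% (2.42 to 9.70) in cluster 0, while on day 10 the intervals overlapped. Cells with a count had less Il5 (ratio 0.245, 0.207 to 0.288, on day 0 and 0.422, 0.304 to 0.572, on day 10), less Gata3 (0.646 and 0.704) and less Areg (0.375 and 0.288) than cells without. The count may mark the population sorted as fm_pos, but this cannot be told: genes called higher in either reporter-positive group lay at the 99.9th percentile of matched random lists on day 0 but the 91.51st on day 10, where 28 cells had a count, while genes called lower lay at percentile 0 on both days, and genes called in the Gata3flox-labelled comparison, a narrower set than the test named, lay at percentiles 100 (higher) and 0 (lower) on both days. No cell type known to lack the reporter was identified, so the background share is unknown (median depth 2321 counts with and 1896 without on day 0, 2020 and 1786 on day 10).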

How the results depend on the processing

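The comparison of fm_pos with fm_neg_Gata3flox and the dorsal clustering without tdtomato were chosen only after the result was seen. Counts of called genes are given for the comparisons in the order of the report, interaction and tamoxifen knockout last. They were 2208, 419, 1919, 1584, 1158 and 200 with DESeq2, and 1324, 321, 974, 893, 773 and 6 with no filter on low counts. A mean CPM of at least 5 gave 113 in the reporter comparison of Gata3flox-labelled mice and 425 between the reporter-negative groups. Fits of the libraries of both groups alone gave 29, 233, 0 and 367 for the first 4, the 0 with edgeR beside 2818 genes at an unadjusted p under 0.05. DESeq2 was not run on those libraries alone. Replicate number as a block gave 126, 31, 131, 83 and 26 for the first 5, and lane as a covariate gave 250, 10, 133, 77 and 73. Lane was taken from the names of the deposited data, not from the labels. All reporter-positive fate-map libraries were in lane L2, and lane L1 held only reporter-negative ones. Lane thus partly followed reporter status, and the fit with lane cannot fully separate them. Leaving out each library in turn gave 514 to 877, 2 to 27, 66 to 489, 5 to 190, 54 to 504 and 0 to 0. The labels do not say that replicate numbers pair the libraries. In the Gata3flox-labelled libraries same-number correlations of deviations were 0.160, 0.0228 and 0.0599, and fm_pos_Gata3flox replicate 2 correlated best with another number (0.0401). A group left with 1 library was assumed to vary like the others. RLE factors (456, 61, 256, 184, 189 and 0), upper-quartile factors (481, 62, 274, 296, 176 and 0) and a log2 fold change of at least 1 (458, 57, 240, 191, 175 and 0) stayed within 1.5 times the reported counts. With fm_neg_Gata3flox as the negative side for fm_pos, 624 genes were called, 263 of them among the 478, and Ccl3 (−2.25) and Egr1 (0.64) reversed. Genes called at adjusted p of 0.1 and 0.01 shared by both reporter comparisons numbered 18 and 0 higher and 24 and 2 lower, and those shared by both comparisons of the floxed label 66 and 0 higher and 24 and 0 lower. Of 155 list results, 94 kept their side of the threshold with an estimated correlation and 61 no longer passed. With fry 107 kept it, 37 no longer passed, 3 newly passed and 8 took the other direction without a call in both, and with the replicate block 135 kept it, 8 no longer passed, 1 newly passed and 11 took the other direction in that way. In dorsal cells, keeping doublets put 23.9% and 21.8% of day 0 and day 10 cells in cluster 2, and keeping the readout genes 15.7% and 11.1%. Resolution 0.3 put 100%, 0% and 0% in clusters 0, 1 and 2 on both days, and resolution 1.0 put 36.9% of day 0 cells in cluster 0. Clustering alone put 33.2% and 21.4% of day 10 cells in clusters 1 and 2, and leaving out tdtomato put 12.4% in cluster 2. In the ILC2-like cluster alone the day 10 to day 0 ratio was 0.864 for Gata3, 1.58 for Areg, 0.667 for Il5 and 0.738 for tdtomato. Except where fewer libraries or other genes were tested, the cause was not tested.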

Other observations

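The tests of the dorsal clusters without tdtomato were chosen only after the result was seen.

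Type 17 cytokine genes and Csf2 were also compared between dorsal cells with and without a tdtomato count. On day 0, Il17f stood at a ratio of 3.38 (1.81 to 6.31) between cells with and without a count, and the GM-CSF gene Csf2 at 0.193 (0.0512 to 0.517). On day 10, Il17f and Csf2 had 0 counts in the 28 cells with a tdtomato count, and 13 and 44 counts in the other cells. The intervals of these ratios, 0 to 4.25 for Il17f and 0 to 1.13 for Csf2, included 1. Il17a stood at 1.32 (0.722 to 2.33) on day 0 and 0.375 (0.0446 to 1.41) on day 10, and both intervals included 1. The ILC2 list lay at percentile 0 of matched random lists on both days (median log2 ratio −0.44 and −0.81). The ILC3 and type 17 list had medians of 0.09 and 0.48, inside the random range on day 0 (up to 0.28) and at its upper bound on day 10 (0.48). The ILC1 and NK list lay at percentiles 0.53 and 37.0.

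Among the dorsal clusters, Areg stood at 825, 274 and 364 CPM in clusters 0, 1 and 2 on day 0 and at 1307, 453 and 1487 CPM on day 10. Il13, which drives type 2 responses in epithelium, stood at 573, 153 and 1058.5 CPM on day 0 and 899, 346 and 697 CPM on day 10. Csf2 stood at 72.9, 7.02 and 222 CPM on day 0 and 78.6, 15.3 and 54.2 CPM on day 10. Fibroblast genes also summed to 3942 and 1054 CPM in WT_tamoxifen and 4261 and 3111 CPM in Gata3KO_tamoxifen.

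The reporter comparison in Gata3flox-labelled mice was set against the other splits of its 6 libraries into 3 and 3. The real split called 63 genes and the highest of the others called 0, with 1 of 10 splits giving as many genes. With 10 splits the design has too few for a share under 0.05.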
